A study of Bacillus subtilis with 6 samples.

How the data were processed

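RNA was sequenced in 6 samples of Bacillus subtilis W168, a tryptophan-prototrophic laboratory strain of this Gram-positive soil bacterium. There were 3 libraries from untreated cells (control) and 3 from cells exposed to an extract of larvae of the black soldier fly, Hermetia illucens (extract). Per the labels' protocols, a culture in LB medium was grown at 37 °C to an optical density at 600 nm of about 0.4 and divided into portions of 25 ml. A portion received the extract at 0.5% by volume for 10 min or was left untreated. The labels describe portions of a divided culture and do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, ribosomal RNA (rRNA) was removed with a hybridisation kit for bacteria, and strand-specific libraries were sequenced on an Illumina instrument.

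The authors deposited raw read counts per annotated feature, made with featureCounts from Subread 2.0.1, per the file headers. The recorded command assigned reads to genes of the BSGatlas annotation with the setting for reverse-stranded libraries, and it named no option for reads that map to several places or overlap several genes. Counts of near-identical genes, such as the rRNA copies, and of overlapping genes are therefore uncertain. Bowtie2 2.4.1, SAMtools, DESeq2 1.28.0, DESeq and deepTools 3.4.3 are named in the submitters' processing notes. The genome build is not given in the sources used here, and positions are printed as the files give them. The authors also deposited a normalized signal per feature, in which each value is the raw count divided by a constant of its library. Those constants lay between 0.890 and 1.14. The authors' deposited table of their own comparison holds p-values, adjusted p-values and log2 fold changes. An adjusted p-value below 0.05 was given for 151 genes in the authors' deposited table, and all 151 had a log2 fold change opposite in sign to extract over control as computed from the deposited normalized values. The fold changes given here were computed from the counts as extract over control, so that a positive value means more RNA with the extract. Of the genes called here, 118 were among those 151.

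The count table held 4773 features, of which 4201 were protein-coding genes, 30 rRNA genes, 63 tRNA genes and 479 other features, and 85 features had no count. Gene names were taken from the authors' deposited table. Locus tags matched 4467 features to a symbol in the RefSeq gene table of assembly ASM904v1, which was used only for names and gene classes. Total counts per library ran from 4900776 to 6580884. Shares of counts are given with Wilson 95% intervals, which cover counting error only.

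Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test on the deposited counts, with filterByExpr, TMM scaling, group as the single factor and Benjamini-Hochberg adjustment over the 4482 genes that passed the filter. Tests were two-sided, and a gene was called at an adjusted p-value below 0.05. Levels are TMM-scaled CPM (counts scaled to library size), as mean ± SD over 3 libraries, and log2 fold changes carry their standard error (SE), the absolute log2 fold change divided by the square root of the F statistic. The common dispersion was 0.0416. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, for lists with at least 3 tested members, with Benjamini-Hochberg adjustment over the lists. The 57 lists hold textbook regulons and pathways of B. subtilis and were fixed before the data were examined, as were the tests, the rule for named genes and the other settings tried, except where stated. Of 859 list entries, 771 were found in the deposited table by name, and 88 were not found under the symbol used and belong to no list as tested, except where stated. The test was checked on simulated counts with the means, library sizes and dispersions of the 4482 genes. It recovered 79% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold, with 9 false calls among 201. The simulated list of changed genes was called, and 0 of 20 lists of unchanged genes were. Simulated genes were drawn independently of each other, whereas the estimated correlation within the LiaRS list, for instance, was 0.98. The simulation therefore does not show how the list test behaves for co-regulated genes. It also gave no library a deviation of its own beyond its size. Recovery and false calls of single genes may therefore differ in the real libraries.

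Genes were named by this rule, applied to protein-coding genes and other features, but not rRNA or tRNA genes, with a mean of at least 10 CPM. Named were the 10 called genes with the largest fold change in each direction whose 3 extract libraries all lay on one side of all 3 control libraries, with at most 3 genes sharing the first 3 letters of their symbol. For each list past the list test, up to 3 called members with the largest absolute fold change were added. A set of anchors was named whatever their result, namely liaI, liaH, bceA, psdA, sigW, sigM, sigX, sigB, des, fapR, fabHB, lcfA, hag, treP, gamP, katA and recA. The anchor des was not found under that symbol and is not analysed here. Genes outside this rule are said to be so where they appear.

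Results were recomputed with RLE size factors, total count scaling, no filter on low counts, a minimum mean of 10 CPM, removal of rRNA and tRNA features, the replicate number as a block, leaving out each library in turn, the Wald test of DESeq2 1.42.0, a threshold of 0.01, limma-trend (limma 3.58.1) on log2(deposited normalized value + 1), camera with an estimated correlation, and the rotation test fry. A fit without control replicates 2 and 3 was added after the data were seen, because these libraries held more rRNA than the others. A list test was likewise added after the data were seen, in which missed entries of the lists past the list test were added by locus tag (14 for Fur, 4 for peptide transporters, 8 for SigW, 6 for SigM and 1 for SigX; the others past the test had none). The missed Zur list entries folEB and zinU were added to that list for 1 comparison of medians, and other missed entries were not added.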

Results

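RNA levels were measured by strand-specific RNA sequencing in 3 untreated control samples and 3 samples of exponentially growing Bacillus subtilis exposed for 10 min to 0.5% (by volume) larval extract of the black soldier fly. Total counts were 6377219, 6397469 and 6320176 in control replicates 1 to 3 and 5076320, 4900776 and 6580884 in extract replicates 1 to 3. Pearson correlations of log2 CPM across genes within a group ran from 0.969 to 0.993, and no pair of libraries agreed within sampling noise. rRNA genes held 0.187% of counts in control replicate 1 (Wilson 95% interval 0.183 to 0.190%), 3.97% in control replicate 2 (3.95 to 3.98%) and 8.57% in control replicate 3 (8.55 to 8.60%). In extract replicates 1 to 3 the rRNA share was 0.264% (0.259 to 0.268%), 0.287% (0.282 to 0.291%) and 0.217% (0.213 to 0.220%). On the first principal component of protein-coding genes, which held 52.8% of the variance, control replicate 1 lay at -28.2, apart from control replicates 2 and 3 at -8.31 and -6.05.

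The comparison of extract with control asks which genes respond to the larval extract. The controls were left untreated, so effects of the larval material and of the addition itself cannot be told apart. All 6 tested genes of the LiaRS envelope stress list and 5 of 9 of the peptide antibiotic transporter list were higher, and all 17 tested genes of the Fur iron uptake list and all 5 of the MntR manganese uptake list were lower. These 4 lists passed camera, and with an estimated correlation the Fur list passed (adjusted p = 0.0264) and the LiaRS, peptide transporter and MntR lists did not (adjusted p = 0.0908, 0.174 and 0.0908). The rotation test fry passed the Fur, LiaRS, peptide transporter and MntR lists (adjusted p = 0.00186, 0.0473, 0.0473 and 0.0114, fry). The steepest rises were in tpeM, tpeL and yxeA, neighbouring genes of an ABC transporter system, and in liaI and liaH, the main targets of the LiaRS envelope stress system. The level of tpeM went from 60.6 ± 12.4 to 15328 ± 4374 CPM (SD, n = 3), 253-fold. Outside the rRNA genes, the steepest falls were in frxB, which encodes a siderophore-binding protein and went from 954 ± 92.7 to 62.1 ± 6.81 CPM, and in ykuO and fldP of a flavodoxin operon. In total 123 of 4482 genes were called by edgeR's quasi-likelihood test, 45 higher and 78 lower. At least 2-fold changes were seen in 101 of them, 32 higher and 69 lower. The calls comprised 42 protein-coding genes higher and 56 lower, 20 rRNA genes lower, and 5 other features. In 103 of the 123 the 3 extract libraries lay on one side of all control libraries, which selection by the same difference favours. With total count scaling 56 genes were higher and 53 lower, 42 of them lower by at least 2-fold, and no rRNA gene was called. Without control replicate 1, 96 genes were higher and 89 lower, and without extract replicate 2, 29 were higher and 47 lower. The count was 185 without control replicate 1, 76 without extract replicate 2, 77 without extract replicate 3 and, in a fit chosen after the data were seen, 350 without control replicates 2 and 3.

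**Figure D1:**
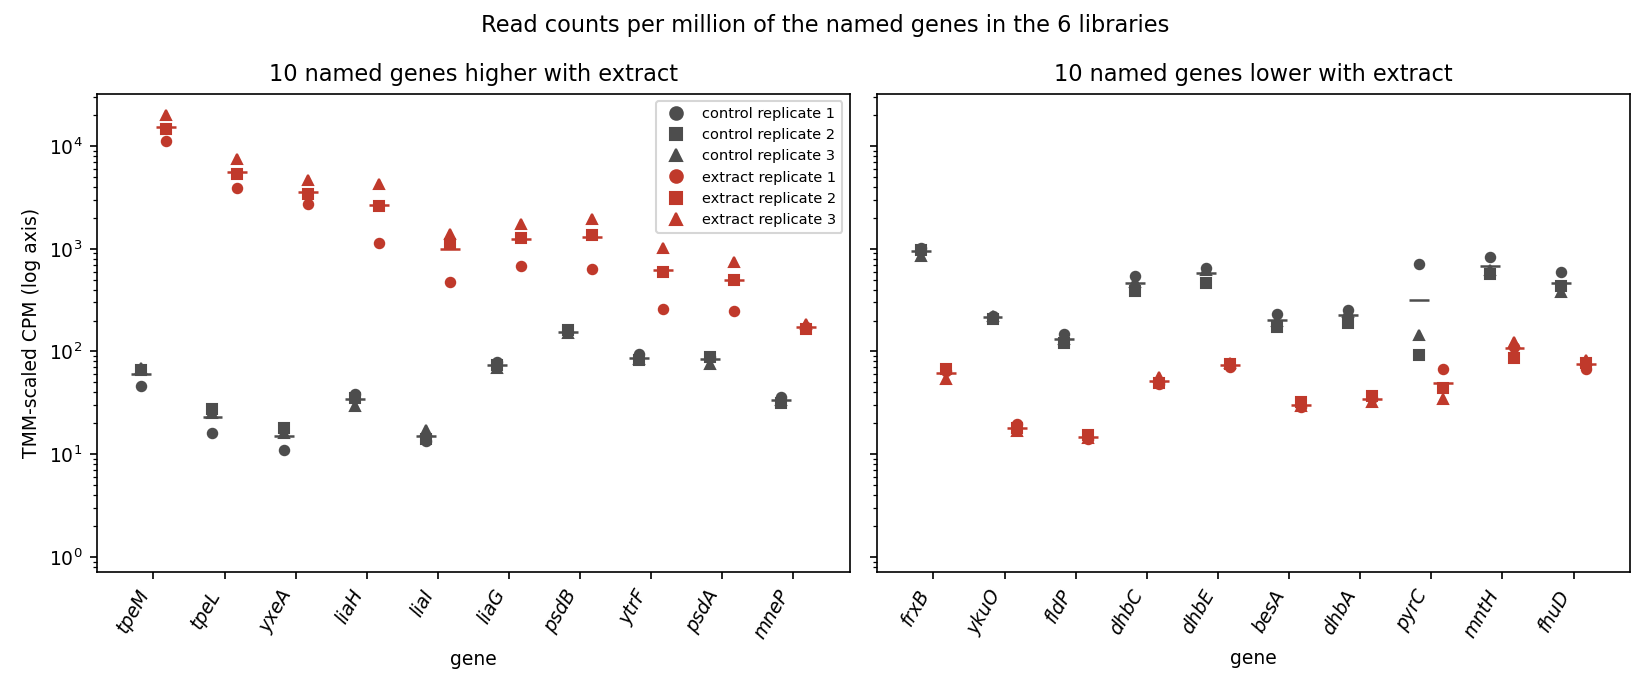
Level of the 10 named genes with the largest rise (left) and the 10 with the largest fall (right), as TMM-scaled CPM on a log axis, with 1 point per library (grey, control; red, extract) and a horizontal line at each group mean. For each gene the 3 extract libraries lie on one side of the 3 control libraries; tpeM has means of 60.6 and 15328 CPM, and pyrC shows the widest spread among controls.

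Every tested member of the LiaRS list, which answers to interference with the lipid II cycle and the membrane, was higher (6 of 6, also 6 adjusted over the list alone). These genes lie together on the minus strand at 3394422 to 3398930. The log2 fold change was 6.27 ± 0.48 (SE, n = 3 per group; adjusted p = 1.05e-05, edgeR) for liaH, a phage shock protein homologue, whose mean went from 34.5 ± 4.58 to 2661 ± 1547 CPM. It was 6.06 ± 0.41 for liaI, its membrane partner (adjusted p = 3.73e-06, edgeR), and 4.06 ± 0.33 for liaG. The list passed camera (adjusted p = 2.13e-44), with adjusted p = 0.0908 with an estimated correlation.

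Of 9 tested members of the list of peptide antibiotic transporters and their regulators, 5 were higher (5 adjusted over the list alone) and 4 were not called; limma-trend called 3, without bceR and bceS. The gene yxeA, at 4068189 to 4068536, had a log2 fold change of 7.89 ± 0.37 (adjusted p = 4.90e-07, edgeR), from 15.1 ± 3.67 to 3585 ± 994 CPM. The ABC transporter genes psdA and psdB, known for resistance to lantibiotics, had log2 fold changes of 2.57 ± 0.33 and 3.07 ± 0.35. The sensor and regulator genes bceS and bceR, which lie outside the naming rule and were chosen after their values were seen, had 0.89 ± 0.21 and 0.85 ± 0.20 (adjusted p = 0.0467 and 0.0447 with edgeR, 0.0181 and 0.0214 with DESeq2, and 0.124 and 0.105 with limma-trend). The bacitracin transporter gene bceA had 0.49 ± 0.21 and was not called (adjusted p = 0.415, edgeR). The list's adjusted p was 6.15e-15 with camera and 0.174 with an estimated correlation. Next to yxeA, tpeM (4068550 to 4070418) and tpeL (4070393 to 4071166) had log2 fold changes of 7.98 ± 0.39 and 7.92 ± 0.40 (adjusted p = 5.47e-07 for both, edgeR). The list as fixed holds these ABC transporter genes and their regulator and sensor genes tpeJ and tpeK under older symbols, which were not found by name; tpeJ and tpeK, which lie outside the naming rule and were chosen after their values were seen, had 0.35 ± 0.16 and -0.13 ± 0.14 and were not called. With these 4 genes added, in a test chosen after the data were seen, 7 of 13 members were higher and 6 were not called, and the list's adjusted p was 3.61e-31 with camera and 0.0681 with an estimated correlation. Outside the lists, ytrF, the last gene of an ABC transporter operon, rose from 86.8 ± 7.07 to 622 ± 377 CPM (log2 fold change 2.84 ± 0.39, adjusted p = 0.00120, edgeR). The genes bceR and bceS follow ytrF on the same strand, with ytrF at 3113979 to 3115289 and bceR at 3113187 to 3113882. Whether their rise is separate from that of ytrF was not tested.

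All 17 tested members of the Fur list of iron uptake genes were lower (17 adjusted over the list alone), with a median log2 fold change of -2.13; the other 14 of its 31 entries were not found under the symbol used. These 14 genes are in the deposited table under newer symbols, and 12 of them were lower and 2, fecE and fecF, which lie outside the naming rule and were chosen after their values were seen, were not called (-0.55 ± 0.16 and -0.46 ± 0.17). Within the operon for the siderophore bacillibactin, dhbC, dhbE and dhbA had log2 fold changes of -3.18 ± 0.18, -2.95 ± 0.18 and -2.72 ± 0.17. Mean dhbC went from 468 ± 76.1 to 51.6 ± 4.62 CPM (adjusted p = 1.07e-06, edgeR). The esterase gene besA, which releases iron from bacillibactin, had -2.74 ± 0.17, and fhuD, for hydroxamate siderophore binding, had -2.62 ± 0.20. The flavodoxin operon gene ykuO, at 1487504 to 1488397, had -3.57 ± 0.16 (adjusted p = 4.90e-07, edgeR), from 217 ± 8.72 to 18.2 ± 1.58 CPM. Its neighbour fldP had -3.19 ± 0.17 and frxB (4067183 to 4068148) had -3.94 ± 0.21 (adjusted p = 6.21e-07 for both, edgeR); both are among these 14. The Fur list was the one list of 56 that held in camera with an estimated correlation (adjusted p = 0.0264; 1.42e-139 with the preset value). With the 14 genes added, in a test chosen after the data were seen, 29 of 31 were lower and 2 were not called. Adjusted over the list alone, all 31 were lower. The adjusted p of this longer list was 1.92e-193 with camera and 0.0421 with an estimated correlation.

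All 5 tested members of the MntR list of manganese uptake genes were lower (5 adjusted over the list alone). The proton-coupled transporter gene mntH, at 491147 to 492424, went from 674 ± 141 to 107 ± 18.5 CPM (log2 fold change -2.65 ± 0.22, adjusted p = 2.04e-05, edgeR). The ABC transporter genes mntA and mntB had -1.21 ± 0.17 and -1.27 ± 0.20. The manganese exporter gene mneP, at 595109 to 596002, rose from 33.6 ± 2.32 to 175 ± 9.93 CPM (2.38 ± 0.15, adjusted p = 2.10e-06, edgeR). The MntR list had an adjusted p of 1.25e-18 with camera and 0.0908 with an estimated correlation.

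**Figure D2:**
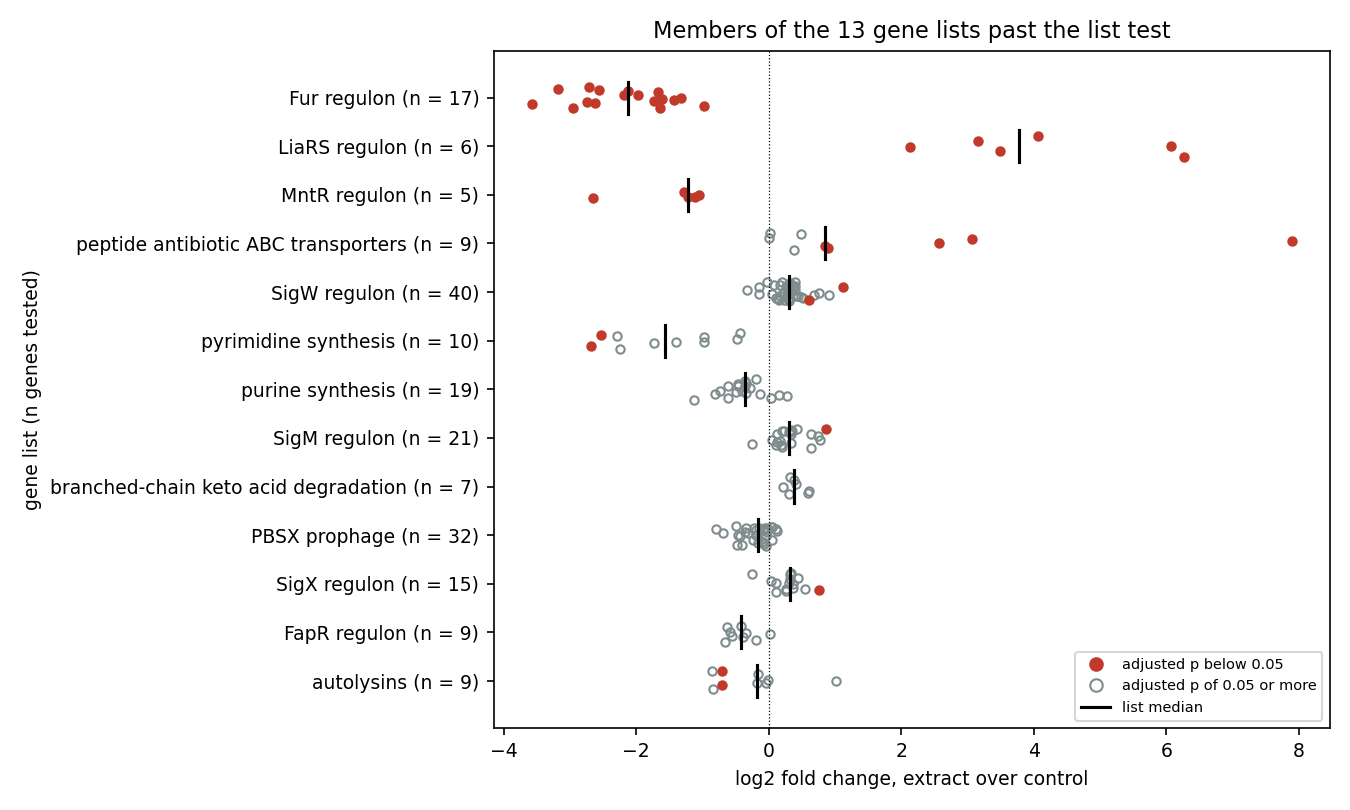
Log2 fold change (extract over control) of each tested member of the 13 gene lists past the list test, 1 point per gene, filled where the adjusted p was below 0.05, with a line at the list median and random vertical offsets. All 17 tested members of the Fur list, of 31 fixed entries, lie below 0 and all 6 of the LiaRS list above 0, and most members of the lower rows are open points.

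The lists of 3 extracytoplasmic sigma factors, which govern envelope homeostasis, passed camera with few called members (adjusted p = 5.42e-05, 0.00398 and 0.0381 for SigW, SigM and SigX), and none passed with an estimated correlation (adjusted p = 0.986 for each). Over 14 other settings with the preset correlation, the SigW, SigM and SigX lists failed to pass in 1, 4 and 5. In the SigW list 2 of 40 members were higher (4 adjusted over the list alone), the flotillin gene floT at 1.12 ± 0.19 and yceG at 0.60 ± 0.14. Another 8 of its 48 entries were not found under the symbol used; under newer symbols 3 of these were higher, nfeDB beside floT at 1.59 ± 0.19 and the transporter genes skiY and skiZ at 0.66 ± 0.14 and 0.58 ± 0.13, which lie outside the naming rule and were chosen after their values were seen. In the SigM list maf, at 0.86 ± 0.20, was the 1 called member of 21 (5 adjusted over the list alone). In the SigX list sigX itself, at 0.76 ± 0.17, was the 1 called member of 15 (2 adjusted over the list alone). Genes for sigW and sigM had log2 fold changes of 0.28 ± 0.23 and 0.34 ± 0.19 and were not called; without control replicate 1 both were called, at 0.62 and 0.57 (adjusted p = 0.0395 and 0.0465, edgeR), and without control replicates 2 and 3, a fit chosen after the data were seen, they had -0.28 and -0.10 and were not called. With missed entries added to the 3 lists, in a test chosen after the data were seen, 5 of 48 SigW, 1 of 27 SigM and 1 of 16 SigX members were higher (7, 7 and 2 adjusted over the list alone), with adjusted p = 3.43e-08, 0.000509 and 0.0257 with camera and 0.986 for each with an estimated correlation. The calls of maf, sigX and yceG were lost with RLE size factors (adjusted p = 0.0820, 0.0722 and 0.158, edgeR).

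Of 10 tested genes of pyrimidine synthesis, 2 were lower (6 adjusted over the list alone). The carbamoyltransferase gene pyrB had a log2 fold change of -2.53 ± 0.58 (adjusted p = 0.0431, edgeR), and the dihydroorotase gene pyrC had -2.69 ± 0.63 (adjusted p = 0.0467, edgeR). The spread among controls was about as large as their mean, with pyrC at 708, 92.9 and 146 CPM in control replicates 1 to 3 and at 68.1, 44.1 and 34.6 CPM in extract replicates 1 to 3. Without control replicate 1 pyrB had -1.41 and pyrC -1.29, both called, and both calls were lost with total count scaling (adjusted p = 0.128 and 0.132, edgeR), DESeq2 (0.0709 and 0.0749) and limma-trend (0.0582 and 0.102). The list had adjusted p = 0.000448 with camera, 0.986 with an estimated correlation and 0.771 without control replicate 1. Among autolysin genes, which encode cell wall hydrolases and their modifiers, 2 of 9 were lower (4 lower and 1 higher adjusted over the list alone), lytC at -0.70 ± 0.15 and lytB at -0.71 ± 0.15; the list had adjusted p = 0.0423 with camera, 0.986 with an estimated correlation and 0.626 without control replicate 1. The calls of lytC and lytB were lost with RLE size factors (adjusted p = 0.0601 and 0.0538, edgeR), although their log2 fold changes stayed at -0.73 and -0.75.

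Another 4 lists passed camera with 0 called members by edgeR. The median log2 fold change was -0.36 over 19 purine synthesis genes (adjusted p = 0.000850), 0.39 over 7 genes of branched-chain keto acid degradation (0.0102), -0.16 over 32 genes of the PBSX prophage (0.0199) and -0.42 over 9 fatty acid synthesis genes under FapR (0.0381). Each had an adjusted p of 0.986 with an estimated correlation. Adjusted over the list alone, 3 of the keto acid degradation genes and 0 of the others passed. At an unadjusted p below 0.05 these 4 lists held 7, 5, 8 and 3 members, and DESeq2 called 1, 0, 1 and 0. The other 43 of the 56 lists did not pass, among them the SigB general stress list (0 of 43 members called), flagella and chemotaxis (0 of 34), ribosomal proteins (0 of 49) and the zinc uptake list under Zur (0 of 6), each by edgeR. At an unadjusted p below 0.05 these held 1, 4, 13 and 0 members, and DESeq2 called 8 ribosomal protein genes and 0 members of the other 3. Of the lists that did not pass, the sugar and polyol uptake list (adjusted p = 0.0930 with camera) alone held called members, 3 of 45 (6 adjusted over the list alone); these were gntR of gluconate use at 2.13 ± 0.47 and the maltose genes malR and malA at 1.11 ± 0.18 and 0.98 ± 0.15, all higher, outside the naming rule and chosen after their values were seen. Of the anchors, sigB had a log2 fold change of 0.24 ± 0.26, the flagellin gene hag -0.03 ± 0.25, the recombination gene recA -0.16 ± 0.20 and the catalase gene katA -0.46 ± 0.18. Values of fabHB and fapR, of fatty acid synthesis, were 0.02 ± 0.21 and -0.42 ± 0.29, and that of lcfA, of fatty acid degradation, was 0.34 ± 0.17. The sugar transporter genes treP and gamP had 0.43 ± 0.26 and -0.56 ± 0.26. None of these anchors was called. Without control replicates 2 and 3, a fit chosen after the data were seen, treP (0.93, adjusted p = 0.0467, edgeR) and fapR (-0.97, adjusted p = 0.0363, edgeR) were called. A missed threshold does not show that they were unaltered.

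Of 28 tested rRNA genes 20 were called lower. None was called with total count scaling, with limma-trend, at a threshold of 0.01 or when any extract library was left out. The mean rRNA share was 4.24 ± 4.20% of counts in controls and 0.256 ± 0.0355% with the extract (SD, n = 3), and control replicate 1 lay below all extract libraries. The median log2 fold change of the rRNA genes was -4.05, and 0.16 without control replicates 2 and 3.

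**Figure D3:**
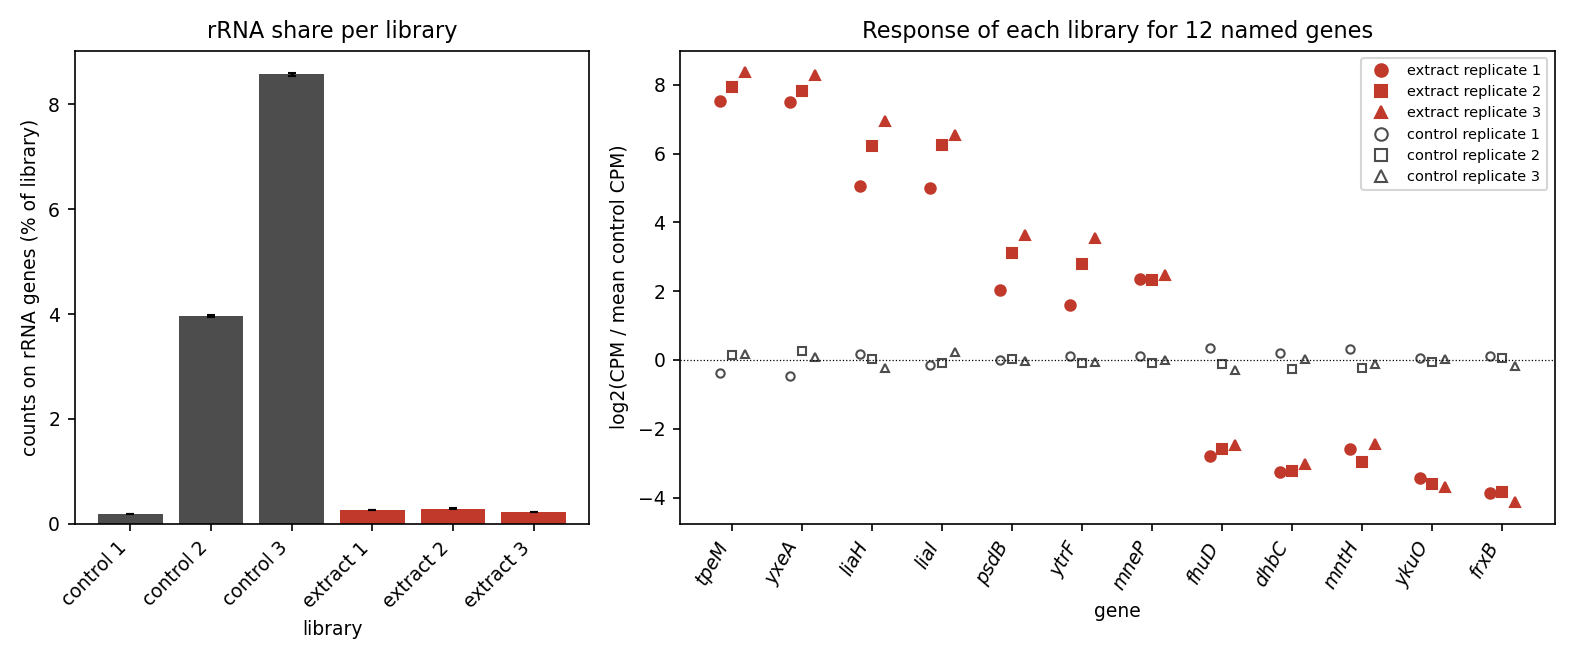
Left, share of counts on rRNA genes in each library (bars, with Wilson 95% intervals); right, log2 of the CPM in each library over the mean control CPM for 12 of the named genes (filled red, extract; open grey, control; marker shape gives the replicate number). Control replicates 2 and 3 hold 3.97% and 8.57% rRNA and the other 4 libraries under 0.3%, and liaH spans 1148 to 4241 CPM among extract libraries while ykuO spans 16.8 to 19.9 CPM.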

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

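Of 29 named genes that were called, 22 stayed called in the same direction under each of the 15 settings fixed before the data were examined that give gene values, and those 22 also did so without control replicates 2 and 3, a fit chosen after the data were seen. The others, maf, sigX, yceG, lytB, lytC, pyrB and pyrC, kept their direction under these settings and lost the call under 8 to 11 of them. Leaving out 1 library gave 76 to 185 called genes (29 to 96 higher, 47 to 89 lower), 69 to 109 changed at least 2-fold (25 to 40 higher, 44 to 75 lower) and 9 to 15 lists. A threshold of 0.01 gave 74 calls (28 higher, 46 lower), of which 44 lower by at least 2-fold. Total count scaling moved the median log2 fold change of all genes from 0.03 to 0.11 and gave 42 genes lower by at least 2-fold, against 69. Its 109 calls shared 91 genes with the 123, and none was an rRNA gene. DESeq2 called 150 genes, 119 of them shared. Without control replicates 2 and 3 the lone control is assumed to vary like the extract group. That fit called 350 genes (126 higher, 224 lower), 222 of them at least 2-fold (91 higher, 131 lower), and 20 lists, and 90 of the 123 genes were shared. There the median of the rRNA genes turned to 0.16 and the SigM list turned lower with an adjusted p of 0.842. Adding the renamed genes to the lists past the list test, chosen after the data were seen, left 13 lists past camera. With the preset correlation the Fur, LiaRS, MntR and peptide transporter lists passed under each fit, and the other 9 lost the call under 1 to 6 of the fits. Camera with an estimated correlation passed 1 list, Fur, and fry passed 4 (Fur, LiaRS, MntR and peptide transporters), against 13. Part of the shifts in genes called lower lies in the rRNA genes, which made up 20 of the 69 genes lower by at least 2-fold. No rRNA gene was called with total count scaling, limma-trend, a threshold of 0.01 or any extract library left out. Beyond the rRNA calls, the cause of these shifts was not tested. Same-numbered libraries had correlations of deviations of -0.01, 0.38 and -0.25, and the 0.38 of the replicates numbered 2 was the highest among all pairs. With 3 libraries per group these values cannot show whether the numbers pair the samples. With a replicate block 146 genes were called, 122 of them shared. In the simulation at this depth 79% of 2-fold changes were recovered, so smaller changes can be missed.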

Other observations

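The gene groups and tests in this part were chosen after the results were seen. Of the 14 entries of the Fur list that the deposited table holds under newer symbols, 12 were lower and fecE and fecF were not called (-0.55 and -0.46). The 12 include all 4 petrobactin uptake genes pbtN to pbtQ, with pbtQ from 1053 ± 247 to 231 ± 66.7 CPM (SD, n = 3; log2 fold change -2.19). They also include fecC at -2.15. The iron uptake gene yhfQ and the heme monooxygenase gene hmoA, which the list as fixed does not hold, were lower, at -2.30 and -1.50. The genes frxB and yxeA, a steep fall and a steep rise, point towards each other on opposite strands with 40 bp between them.

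Of 7 tested features of the ytr operon, 5 were higher, from ytrB at 1.05 to ytrF at 2.84; ytrA (0.79) and a feature without a symbol (-0.33) were not called. In the yxe operon for sulfur compound use 6 of 7 genes were lower, with yxeN at -1.41. The cytochrome P450 gene cypB (1.17), its regulator gene bscR (1.16) and yrhH (1.00) of the same operon were higher, as were ywoB, ywoC and ywoD (1.12, 1.68 and 1.59) and the maltose genes malA and malR (0.98 and 1.11), while malP of the same operon had 0.85 and was not called. The 98 called protein-coding genes fell in 48 annotated operons where an operon was given; 23 operons held at least 2 called genes, 72 in all, and 0 operons held calls in both directions.

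The induced genes differed in level among extract libraries. Over 30 protein-coding genes that rose at least 2-fold, extract replicate 3 was above replicate 1 in 29, by a median of 1.91-fold, whereas over 48 that fell at least 2-fold the median was 1.11-fold. Library scaling shifts both sets alike, and the medians differed by 0.782 on the log2 scale (bootstrap 95% interval 0.42 to 1.13 over genes, which are not independent), and by 0.36 with 1 value per operon (0.55 over 13 induced operons, 12 of them above 0, and 0.19 over 21 lowered; interval 0.17 to 1.05), which argues against it. Untreated RNA mixed into extract replicate 1 would shrink the falls as well as the rises; replicate 1 showed 0.401 of the change in replicate 3 over the induced genes and 1.04 of it over the lowered genes (1.00 to 1.10), and by operon 0.544 and 1.04. A difference in exposure between the portions may remain, but it would have to weaken the rises in replicate 1 and leave the falls as large. That was not tested, nor was any biological explanation.

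The fall of iron and manganese uptake genes may reflect metals supplied with the extract. All 22 tested members of the Fur and MntR lists stayed lower and called under each of 3 scalings. The median log2 fold change of all genes ran only from 0.003 with RLE to 0.11 with total count scaling. The 22 members lay at -3.57 to -0.98, so these scalings differ too little to have undone their calls. The fall therefore does not rest on the choice among the 3, and the comparison cannot test scaling beyond that. Added manganese would raise the exporter genes mneP and mneS, and both were higher (2 of 2, at 2.38 and 1.33). Both values were known before the test was chosen. Whether their rise is separate from the fall of the MntR list was not tested. It therefore does not tell added manganese from another change in MntR activity. The fall of iron and manganese uptake genes did not extend to the Zur list with folEB and zinU. Its median was 0.169 (SD 0.30, 8 genes), and 0.22 over the 6 tested list members without these additions, against -1.86 for the Fur and MntR lists. Whether the Zur genes had room to fall from their control level was not examined, so this does not settle whether metal uptake fell in general. Metal content was not measured, and other changes in Fur and MntR activity stay open.

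The lower rRNA counts with the extract are a candidate artefact of uneven rRNA content among controls. The highest control share was 45.9 times the lowest, more than the 16.6-fold ratio of the group means. Control replicate 1, at 0.187%, lay below all extract libraries. An exact permutation test of the log2 share gave p = 0.400, two-sided, but 0.1 is the smallest this design allows, so that test decides nothing. Ribosomal RNA was removed during library preparation, so the share left also depends on how well removal worked and does not measure rRNA in the cells. A fall caused by the extract stays open.

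The 6 samples can be split 3 against 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes control and extract libraries on both sides. Genes that differ between the groups then widen the spread within each side, and part of the group difference stays. These splits therefore do not show what would pass without an effect of the extract, for genes or for lists. The real split gave 123 called genes and the highest other split 0; as large a count came from 1 of 10 splits. At an unadjusted p below 0.05, edgeR gave 481 genes for the real split and 18 to 350 for the others; DESeq2 was not run on them. For genes changed at least 2-fold the counts were 101 and 0, again 1 of 10. For lists the real split gave 13 and the highest other 21, and 7 of 10 splits reached 13. In the other 9 splits camera with the preset correlation passed the pyrimidine synthesis list 9 times, the Fur list 7, purine synthesis 6, the LiaRS, MntR, SigM and FapR lists 5 each, SigW and PBSX 4 each, the peptide transporter list 3, SigX and autolysins 2 each and keto acid degradation 1.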
